A study of Bos taurus with 6 samples.

How the data were processed

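Total RNA of bovine conceptuses (the embryo with its extraembryonic membranes) was measured on 6 single-channel Affymetrix bovine expression arrays, 3 for day 20 and 3 for day 22 of pregnancy. Per the labels' protocols, 30 embryos were placed in the uteri of 15 Holstein heifers on day 7, 2 to a recipient, and conceptuses were later flushed from the uterus. Labelled RNA was made from 100 ng of total RNA. The labels give the cell type as trophoblast and the tissue as conceptus. They do not say whether a sample was 1 conceptus or a pool, or whether samples came from separate recipients, so p-values measure the spread between these samples only.

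The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization and a summary over the probes of a set), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The medians of the arrays ranged from 5.33 to 5.43 and the highest values from 14.1 to 14.5. RMA gives no detection call, and the low end of its scale compresses differences. The 25th percentile of the probe set means, 3.57, therefore served as a guide to low signal. The number of arrays limits the precision.

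The table held 24128 probe sets. After 112 control probe sets were left out, 24016 were tested. In the platform annotation 13292 of these had 1 gene symbol, 86 had several and 10638 had none listed. Probe sets with several symbols were not named. Symbols were updated through the gene table of the ARS-UCD2.0 assembly, used for names only because no build is named for the array. Of the probe sets with 1 symbol, 13263 matched by gene identifier, 2 by accession, and 27 kept the symbol of the annotation, with 1 symbol changed. The named probe sets stood for 9155 genes, each represented by its probe set with the highest mean over the 6 arrays.

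Day 22 was compared with day 20 by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes, a two-sided test and Benjamini-Hochberg adjustment over 24016 probe sets at a threshold of 0.05. Every adjusted p of a gene in the text is from that limma test unless another is named. Log2 changes are day 22 minus day 20. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists with at least 3 measured genes. Of the 28 lists fixed, the interferon tau list had 1 measured gene, which is given alone. Each list was also tested with a correlation estimated from the data, and with fry. The distance between days was tested by an exact permutation of the day labels. On simulated arrays of day 22 against day 20 with 24016 probe sets, the limma test recovered 32% of planted log2 changes of 1, 74% of 2, 90% of 3 and 94% of 4, with 3 false calls among 23816 probe sets. It made 0 calls where nothing was planted. Only 50 probe sets of each size were planted, whereas 29.1% of probe sets passed in the real data. The adjustment is stricter when few probe sets change, so these shares do not give the recovery in the real data. In simulated lists over 9155 genes, camera called 25 of 25 shifted lists and 0 of 175 unshifted ones. The simulated genes were drawn independently, whereas estimated correlations in the real lists reached 0.564. That simulation therefore does not test the calls made at the preset correlation.

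The design, the lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold whose days did not overlap, and up to 4 genes of each list by size of change. It gave 111 genes, of which 13 had a day mean below 3.57. Members that moved against the rest of their list, and other genes outside the rule, were chosen after their values were seen. A fit with an index of RNA integrity as a covariate was also added after the data were seen. The index is the mean, over 5 control transcripts (actin, GAPDH, EEF1A1, PPIB and EIF4E), of the log2 value of the 3-prime probe set minus that of the 5-prime probe set. A higher index was read as a greater loss of 5-prime sequence, which would raise the difference for each of the 5 transcripts. Alternatives were the replicate number as a block, each array left out in turn, filters on low probe sets, other scalings, array weights, other tests, other thresholds, and the mean of all probe sets of a gene. Scan dates and batches are not given in the sources used here, so no batch was tested. Probe sets for pregnancy-associated glycoproteins, prolactin-related proteins and interferon tau can cross-hybridize with near-identical family members.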

Results

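Gene expression was measured in conceptuses at day 20, when attachment to the uterus is starting, and at day 22, when it is tight, to find genes associated with implantation. Each day had 3 arrays. The values are log2 expression per probe set, and errors are SDs over n = 3 arrays unless a standard error (SE) is named.

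Most measured genes of proteins secreted by the trophoblast were lower at day 22 than at day 20, and most matrix, mesenchymal and endoderm genes were higher. Of 27 lists tested, 11 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.49). Of 24016 probe sets, 6988 (29.1%) passed the limma threshold, 3158 higher and 3830 lower at day 22. Of these, 3648 changed at least 2-fold, 1894 higher and 1754 lower. By gene, 1364 were higher and 1798 lower of 9155. The median log2 change of all probe sets was -0.098. The 3 values of the days did not overlap for 46.9% of probe sets, against 10% by chance. Arrays of the same day correlated at 0.9808 ± 0.0068 across probe sets (SDs here are over pairs, which share arrays). Those of different days correlated at 0.9107 ± 0.022. The difference of 0.0701 had an exact permutation p of 0.1, the share of splits with a difference as large or larger, and the smallest possible with 10 splits. The first principal component held 77.2% of the variance and parted the days.

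Most of the 12 largest increases were in genes of plasma proteins, matrix or mesenchyme. ORM1, an acute-phase plasma protein, rose from 5.37 ± 4.02 to 12.57 ± 1.29 (log2 change 7.20, SE 1.85, adjusted p = 0.0264). AQP1, a water channel, rose by 6.34 from a day 20 mean of 5.66 ± 2.36, an 81.1-fold change (adjusted p = 0.00586). The proteoglycans LUM and DCN rose by 6.28 and 6.26, and COL6A1, a collagen chain, by 6.22. A2M, a protease inhibitor of plasma, rose by 6.10, APOB by 6.01, CDH11 by 5.92, VIM by 5.87, TTR by 5.81, TF by 5.71 and COL1A2 by 5.59, and the adjusted p of these ranged from 0.00604 to 0.031. Day 20 arrays differed widely for these genes, with SDs of 1.91 to 4.02. ORM1, APOB, VIM, TF and COL1A2 each missed the threshold without at least 1 of the arrays. By the unmoderated equal-variance test none of the 12 passed, with adjusted p from 0.0561 to 0.132. The index of RNA integrity also differed, at 0.838 ± 0.203 on day 20 and 1.096 ± 0.196 on day 22. Its transcripts did not move alike: the 3-prime minus 5-prime difference rose for EEF1A1 (-2.42 to -1.45) and EIF4E (3.05 to 3.46), was 0.18 and 0.28 for GAPDH, and was lower at day 22 for actin (1.69 to 1.60) and PPIB (1.68 to 1.60). With it as a covariate ORM1, LUM, DCN, A2M, APOB, CDH11, VIM, TTR, TF and COL1A2 no longer passed, with 1 residual degree of freedom fewer. Their log2 changes were then 6.07, 5.16, 5.48, 5.19, 4.41, 5.02, 4.78, 4.96, 3.70 and 4.59 in that order, with adjusted p from 0.0586 to 0.182.

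The largest decreases were more even between arrays at day 20. STC1, a secreted glycoprotein hormone, fell from 10.37 ± 0.35 to 5.11 ± 1.19 (38.1-fold, adjusted p = 0.000905). SECTM1, a secreted and transmembrane protein, fell from 11.59 ± 0.09 to 6.35 ± 1.54 (37.8-fold, adjusted p = 0.00193). BCL2A1, an inhibitor of apoptosis, fell by 4.91 on the log2 scale and PGF, placental growth factor, fell by 4.58. ACSM2B fell by 4.57, CPA5 fell by 4.56, and ATP8A1 fell by 4.23. The iodide transporter SLC5A5 fell by 4.51 and the bile acid transporter SLC10A1 fell by 4.46, the latter to a day 22 mean of 2.55, below the low-signal guide of 3.57. PAG9, PAG7 and CSH2 complete the 12 and belong to the families described next.

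**Figure D1:**
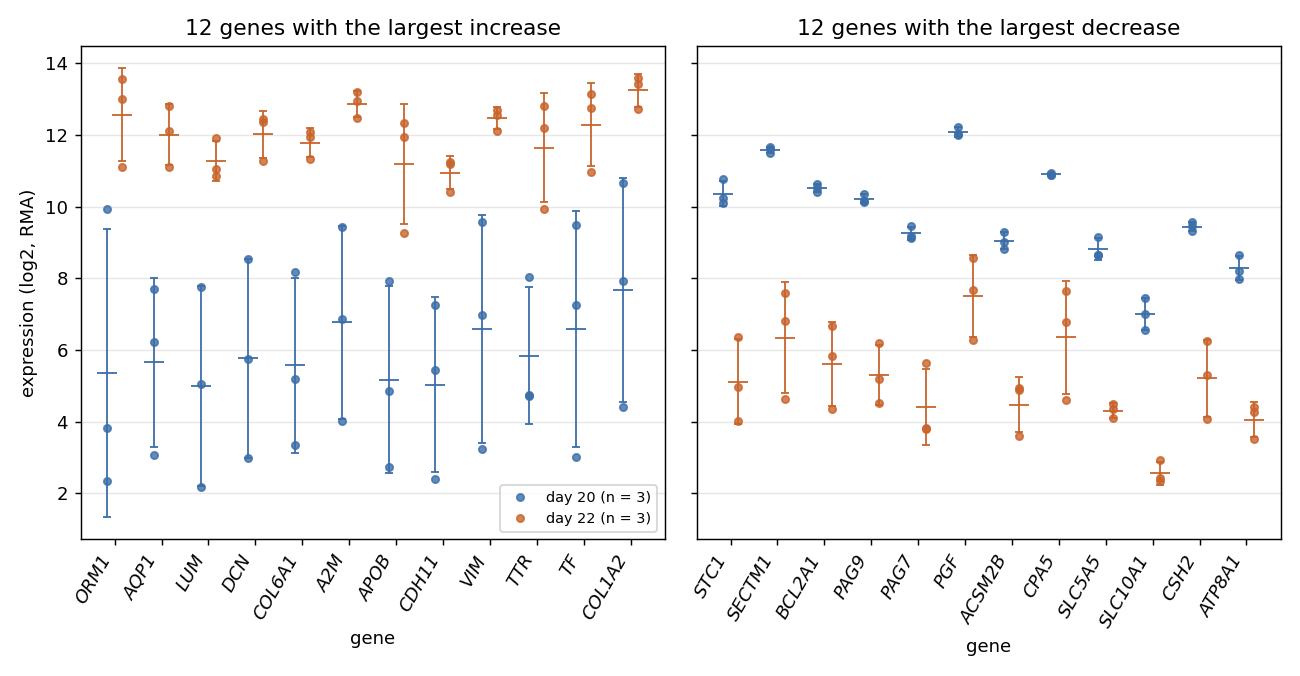
Log2 expression of the 12 genes with the largest increase and the 12 with the largest decrease, with each array as a point and the mean and SD of each day (n = 3) as a line and bars. The rising genes spread widely at day 20, as for ORM1 at 5.37 ± 4.02, while the falling genes were close together at day 20, as for SECTM1 at 11.59 ± 0.09. Most of the falling genes spread more at day 22, as for SECTM1 at 6.35 ± 1.54.

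Genes of secreted trophoblast proteins fell together. Of 19 measured pregnancy-associated glycoproteins, aspartic protease relatives secreted by the ruminant trophoblast, 18 fell and 0 rose (19 and 0 adjusted over the list alone). PAG9 fell from 10.22 ± 0.12 to 5.30 ± 0.85 (30.1-fold, adjusted p = 0.000358), and PAG7 from 9.25 ± 0.17 to 4.42 ± 1.06 (28.6-fold). The list median was -3.05 (camera adjusted p = 1.26e-08; adjusted p = 0.49 with an estimated correlation). Of 7 placental lactogen and prolactin-related genes, 6 fell and 0 rose (6 fell and 1 rose adjusted over the list alone), with a median of -3.46 (camera adjusted p = 0.0373; adjusted p = 0.494 with an estimated correlation). CSH2, a placental lactogen, fell from 9.45 ± 0.12 to 5.21 ± 1.08, and PRP1 from 11.39 ± 0.05 to 7.80 ± 1.61. That list's adjusted p was 0.0508 without day 22 replicate 3 and 0.138 with only probe sets above the median, and 2 members fell by the unmoderated test. The 1 measured interferon tau gene, IFNT2, which encodes the signal of pregnancy recognition in ruminants, fell from 14.18 ± 0.08 to 11.05 ± 0.53 (8.70-fold, adjusted p = 0.000396). Of 10 other binucleate trophoblast and fusion genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -2.08 and a camera adjusted p of 0.0539, but 0.0421 without day 20 replicate 3, 0.0102 without day 22 replicate 2 and 0.046 with quantile normalization. HPSE, a heparanase, fell by 3.38 and TKDP1, a trophoblast Kunitz domain protein, fell by 2.59. SULT1E1 and SLC1A5 rose by 1.26 and 2.02. The index of RNA integrity was 0.258 higher at day 22, 1.29 within-day SDs. With it as a covariate the median of the glycoproteins was -2.93 (camera adjusted p = 6.06e-08) and 16 of the 18 still passed.

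Transcription factors of the trophoblast and epithelial genes fell as well. Among 14 measured trophoblast transcription factors 7 fell and 1 rose (7 and 3 adjusted over the list alone), with a median of -1.34 (camera adjusted p = 0.0373; adjusted p = 0.49 with an estimated correlation). PPARG, a nuclear receptor of lipid metabolism, fell from 9.09 ± 0.32 to 4.88 ± 0.47 (18.4-fold, adjusted p = 0.00024), TFAP2A fell by 3.62, DLX5 fell by 3.40 and ASCL2 fell by 3.00. KLF5 rose by 1.79. The call on this list was lost without day 20 replicate 2 (adjusted p = 0.054), day 22 replicate 1 (0.0536) or day 22 replicate 3 (0.0647). It was also lost with the index of RNA integrity, 0.258 higher at day 22, as a covariate (0.0517), where the median was -1.19 and 7 members were still counted as lower, and with only probe sets above the median, where the list median was -0.37 (0.168). Of 22 epithelial junction and keratin genes, 13 fell and 4 rose (14 and 5 adjusted over the list alone), with a median of -1.28 (camera adjusted p = 0.0272; adjusted p = 0.49 with an estimated correlation). The adherens junction cadherin CDH1 fell from 11.23 ± 0.10 to 7.71 ± 0.95 and the tight junction claudin CLDN1 fell by 3.72. KRT7, a keratin, fell by 2.83 and CLDN6 fell by 2.60. The desmosome genes PKP2 and DSC2, the keratin KRT18 and the cadherin CDH3 rose by 0.71, 0.77, 0.76 and 1.25, and 2 members rose without any 1 of the day 20 arrays or day 22 replicate 2. With only probe sets above the median the epithelial list had an adjusted p of 0.0505.

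Matrix and mesenchymal genes rose. Of 35 collagens and other matrix genes, 25 rose and 2 fell (27 and 2 adjusted over the list alone), with a median of 3.53 (camera adjusted p = 2.54e-08; adjusted p = 0.49 with an estimated correlation). COL6A1 rose from 5.57 ± 2.45 to 11.79 ± 0.41 (74.5-fold, adjusted p = 0.00604) and LUM from 5.00 ± 2.79 to 11.28 ± 0.57. MGP and THBS2 fell by 1.93 and 0.43, but 1 member fell without any 1 of the 6 arrays. By the unmoderated test 12 members rose. Of 13 mesenchymal genes, which include regulators of the epithelial to mesenchymal transition, 8 rose and 3 fell (9 and 3 adjusted over the list alone), with a median of 2.14 (camera adjusted p = 0.011; adjusted p = 0.49 with an estimated correlation). The intermediate filament gene VIM rose from 6.59 ± 3.18 to 12.46 ± 0.31 (adjusted p = 0.0202), ACTA2, a smooth muscle actin, by 4.13 and the growth factor receptor PDGFRA by 4.52 from a day 20 mean of 3.52, below the low-signal guide. THY1, MSN and S100A4, a surface glycoprotein, an actin linker and a calcium-binding protein, fell by 0.46, 0.76 and 1.00, and 1 member fell without day 20 replicate 1, day 20 replicate 2, day 22 replicate 1 or day 22 replicate 3. With only probe sets above the median the mesenchymal list had an adjusted p of 0.0569. With the index of RNA integrity as a covariate, which differed by 0.258 between the days, 15 of the 25 matrix genes still passed as higher, with a list median of 2.55 (camera adjusted p = 3.7e-06).

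Endoderm and yolk sac markers rose, and the number that passed depended on single arrays and on the test. Of 31 measured, 19 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 3.38 (camera adjusted p = 7.44e-07; adjusted p = 0.49 with an estimated correlation). The lipoprotein gene APOB rose from 5.17 ± 2.61 to 11.19 ± 1.67 (adjusted p = 0.0163) and TTR, a thyroid hormone carrier, from 5.83 ± 1.91 to 11.64 ± 1.52 (adjusted p = 0.0075). TF, the plasma iron carrier transferrin, rose by 5.71 and APOC2 by 5.24. ALB fell by 0.48, but 0 members fell without day 20 replicate 2 or 3 or day 22 replicate 1 or 3. Only 10 members passed as higher without day 20 replicate 3, and 7 without day 22 replicate 2 or day 22 replicate 3. By the unmoderated test 1 rose, and by the trend and robust fit 13. With the index of RNA integrity, 0.258 higher at day 22, as a covariate, 4 of the 19 passed and the median was 1.91 (camera adjusted p = 8.34e-05).

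Some vascular and mesoderm markers also rose, though most endothelial markers did not pass. Of 18 endothelial markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 0.000677; adjusted p = 0.49 with an estimated correlation), and 12 rose without day 22 replicate 1 but 4 without day 20 replicate 1 or 3 or day 22 replicate 2 or 3. FLI1, a transcription factor, rose by 4.74, PLVAP, a protein of endothelial diaphragms, by 3.94, LYVE1 by 3.74 and the receptor TEK by 3.63. The days overlapped for LYVE1, whose adjusted p of 0.0357 became 0.0937 to 0.113 without day 20 replicate 1 or 3 or day 22 replicate 2 or 3. Of 8 mesoderm and allantois markers, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.0373; adjusted p = 0.49 with an estimated correlation). BMP4, a secreted growth factor, rose from 5.70 ± 1.00 to 8.87 ± 0.26 and PITX1 by 2.90. Without day 20 replicate 2 or day 22 replicate 3 that list's adjusted p was 0.054 and 0.0536. With the index of RNA integrity, 0.258 higher at day 22, as a covariate it was 0.0517, with a median of 1.03 and 4 higher members, and 3 endothelial markers rose, with a list median of 0.66. Of 14 embryonic blood markers, GYPC and LMO2 rose by 3.46 and 3.13 and ALAS2, an enzyme of heme synthesis, fell by 2.32 (2 and 1 adjusted over the list alone; camera adjusted p = 0.061). Without day 22 replicate 1, 7 blood markers rose and the adjusted p was 0.0123. Of 6 embryonic disc markers, 1 rose, ZIC2 by 3.14 (1 and 0 adjusted over the list alone). The pluripotency factor POU5F1 had a log2 change of 0.66 (adjusted p = 0.264), and the list, with a median of -0.23 and a mean of 0.46, had a camera adjusted p of 0.868.

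**Figure D2:**
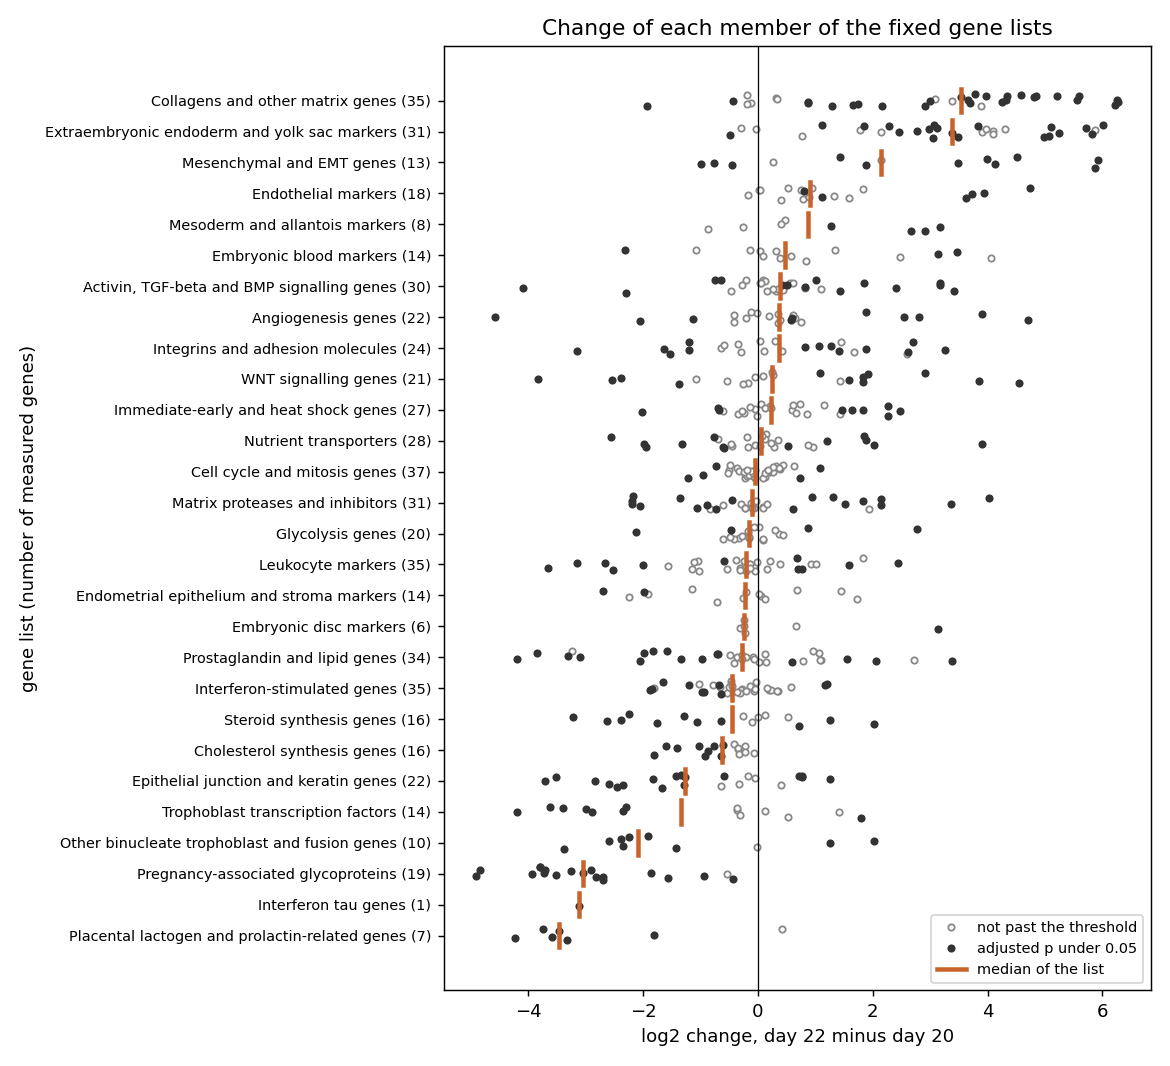
Log2 change from day 20 to day 22 of each measured gene of the 28 fixed lists, with genes past the threshold filled, others open, and the list median as a bar. Matrix and endoderm lists lie to the right, with medians of 3.53 and 3.38, and glycoproteins and placental lactogens to the left, at -3.05 and -3.46.

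Endometrial and leukocyte markers, taken as a guide to the dam's tissues, did not rise as groups. Some were high at day 20, so their fall cannot show that cells of the dam were absent. Of 14 endometrial markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone), PTGFR by 2.71 and LGALS9 by 1.98 on the log2 scale, with a list median of -0.23 (camera adjusted p = 0.473). Of 35 leukocyte markers, 5 rose and 6 fell (5 and 7 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.532). CD14, a receptor for bacterial lipopolysaccharide, fell from 7.30 ± 0.08 to 3.65 ± 0.55, and AIF1 fell by 2.66. Without day 22 replicate 1, 2 endometrial markers rose, and without day 20 replicate 1, 6 fell. Without day 20 replicate 1 or 3 or day 22 replicate 2 or 3, 3 leukocyte markers rose. Of 35 interferon-stimulated genes, 2 rose and 8 fell (2 and 8 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.126, but 0.0239 without day 20 replicate 1 and 0.0125 with the integrity covariate). TRIM21 fell by 1.88 and RSAD2 fell by 1.84, while IFIT5 and UBA7 rose by 1.20 and 1.17. Just 1 member rose without day 20 replicate 1 or 2 or day 22 replicate 2 or 3. Without day 20 replicate 2, day 22 replicate 1 or day 22 replicate 3, 5 members fell, and RSAD2, IFI6 and TAP1 each missed the threshold without at least 1 array.

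Signalling and adhesion genes moved both ways. Of 30 activin, TGF-beta and BMP genes, 10 rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.0272; adjusted p = 0.49 with an estimated correlation). The growth factor TGFB3 fell from 9.79 ± 0.09 to 5.70 ± 0.44, and the receptor TGFBR2 and the matrix protein TGFBI rose by 3.17 and 3.41. Without day 22 replicate 1 that list had 6 higher members and an adjusted p of 0.0708, and with only probe sets above the 25th percentile the adjusted p was 0.0528. Of 24 integrins and adhesion molecules, 8 rose and 5 fell (10 and 5 adjusted over the list alone; median 0.36; camera adjusted p = 0.183). CD44, a hyaluronan receptor, rose by 3.27 and VCAM1 by 2.70, and ITGB2 fell by 3.15. Without day 20 replicate 1 or day 20 replicate 2, 5 members rose. Of 21 WNT genes, 8 rose and 4 fell (9 and 4 adjusted over the list alone; median 0.25; camera adjusted p = 0.258), with WNT2B higher by 4.54 and WNT6 lower, at 8.31 ± 0.06 and 4.47 ± 0.11. Of 22 angiogenesis genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone; median 0.37; camera adjusted p = 0.0841, and 0.0213 without day 22 replicate 1). NRP1 and FLT1, receptors for vascular endothelial growth factors, rose by 4.70 and 2.81. Of 31 matrix proteases and inhibitors, 9 rose and 9 fell (10 and 9 adjusted over the list alone), with a median of -0.11, a mean of 0.15 and a camera adjusted p of 0.934. The gelatinase MMP2 rose by 4.02 and the cathepsin CTSL fell by 2.19.

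Among metabolic genes the cholesterol pathway fell as a group. Of its 16 genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.00139; adjusted p = 0.49 with an estimated correlation), and 5 fell without day 20 replicate 3. CYP51A1, a sterol demethylase, fell from 10.73 ± 0.05 to 9.13 ± 0.30 (3.04-fold, adjusted p = 0.000989) and TM7SF2 fell by 1.82. The adjusted p of TM7SF2 was 0.0526 without day 20 replicate 3 and 0.0858 by the unmoderated test. Of 16 steroid synthesis genes, 8 fell and 3 rose (8 and 4 adjusted over the list alone; median -0.45; camera adjusted p = 0.216). STAR, which brings cholesterol into mitochondria, fell by 3.22 and CYP11A1, the side-chain cleavage enzyme, fell by 2.25, while CYP17A1 rose by 2.02. Of 34 prostaglandin and lipid genes, 12 fell and 4 rose (13 and 4 adjusted over the list alone), with a median of -0.28 and a camera adjusted p of 0.258. With only probe sets above the median that list had a median of -0.719 and a camera adjusted p of 0.0478. PTGS2, a cyclooxygenase, fell from 12.03 ± 0.29 to 8.18 ± 0.78, and the lipase LPL rose by 3.38. Of 20 glycolysis genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; median -0.15; camera adjusted p = 0.895), among them PFKM, higher by 2.77, and ALDOC, which fell by 2.12. Without day 20 replicate 2 or 3 or day 22 replicate 2 or 3, 1 glycolysis gene fell. Of 28 nutrient transporters, 6 rose and 7 fell (7 and 7 adjusted over the list alone; median 0.06; camera adjusted p = 0.739). The glutamate transporter SLC1A3 rose by 3.90 and SLC1A4, a carrier of neutral amino acids, fell by 2.56. Without day 20 replicate 2, 4 transporters fell.

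Few proliferation genes passed the threshold. Of 37 cell cycle genes, 2 rose and 3 fell (1 and 3 adjusted over the list alone). Their median was -0.05, camera gave the opposite direction, and its adjusted p was 0.658. TYMS, a thymidylate synthase, rose by 1.08 and CCNE1 fell by 1.21. Without day 22 replicate 1, 6 members fell and 1 rose, and 1 rose also without day 20 replicate 1 or 3 or day 22 replicate 2. Of 27 immediate-early and heat shock genes, which respond to handling of tissue, 6 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.22; camera adjusted p = 0.0841). CCN2, EGR1 and DUSP1 rose by 2.48, 2.27 and 2.26, and IER3 fell by 2.03. Without day 22 replicate 3, 2 members rose and CCN2, EGR1 and DUSP1 missed the threshold, and without day 20 replicate 2 the list's adjusted p was 0.0332. In both cases 1 member fell.

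**Figure D3:**
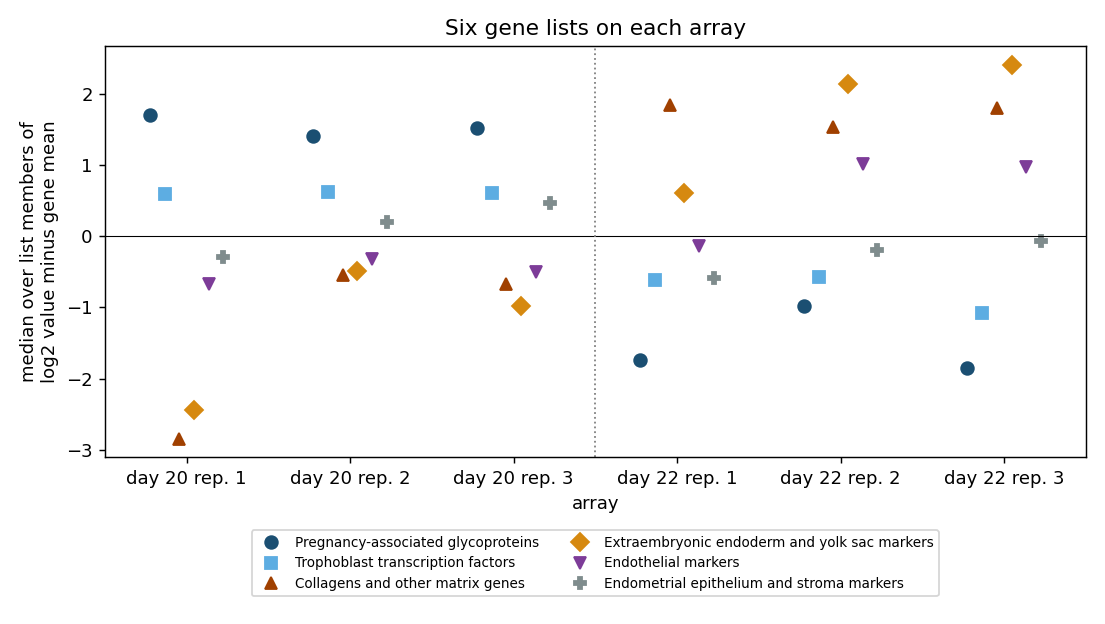
Median, over the members of 6 gene lists, of the log2 value minus the gene's mean over all arrays, for each array. Day 20 replicate 1 lies lowest for matrix and endoderm genes, at -2.84 and -2.43, while the trophoblast transcription factors lie between 0.59 and 0.62 on the day 20 arrays.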

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

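The total of 6988 probe sets stayed within 1.5 times under the other scalings, filters, array weights, the trend and robust fit and the looser threshold. Median centring called 7525, of which 37.5% were higher, against 45.2% of the main count. The unmoderated equal-variance test called 1814 as higher, and 33 of the 111 named genes lost their call, among them the 12 with the largest increase and PRP1, PRP3 and PRP4. Under it endoderm markers counted as higher went from 19 to 1, matrix genes from 25 to 12, and placental lactogens counted as lower from 6 to 2. The mean of all probe sets of a gene gave 3281 changed genes (1357 higher and 1924 lower), fewer because fewer features were tested. A change of at least 2-fold left 3648 (1894 and 1754) and a threshold of 0.01 left 3709 (1644 and 2065), both by construction. The integrity covariate, chosen after the data were seen, left 4377 (1901 and 2476), with 1 residual degree of freedom fewer, and 20 of the 111 named genes lost their call. Members counted as higher with it were 5 mesenchymal (8 in the fit without it), 4 adhesion (8), 5 WNT (8), 4 angiogenesis (7), 3 transporter (6), 2 immediate-early (6), 2 leukocyte (5), 2 epithelial (4), 3 endothelial (6), 1 interferon-stimulated (2), 1 other binucleate (2), 0 steroid (3, CYP17A1 among them) and 0 trophoblast transcription factor genes (1, KLF5). Leaving out 1 array gave 4953 to 6596 probe sets, 2269 to 3008 higher and 2684 to 3588 lower, 8 to 12 lists and a difference in correlation of 0.0603 to 0.0798. Of the 110 named genes past the threshold, 15 lost the call without at least 1 array and 0 reversed. For ORM1 the adjusted p then reached 0.0909, for APOB 0.0608, for VIM 0.064, for TF 0.0989 and for COL1A2 0.0726. Of the lists, 11 passed with the preset correlation, 0 with an estimated correlation (lowest adjusted p 0.49) and 18 by fry, which asks another question. Fry gave the opposite direction to camera for matrix proteases (median -0.111, fry adjusted p = 0.0122) and for WNT genes (median 0.251, fry adjusted p = 0.0131), neither past the threshold by camera, and the cause was not tested. The trophoblast transcription factors and the placental lactogens missed the threshold with median centring (adjusted p = 0.0621 and 0.0588). With only probe sets above the median, the mesenchymal (0.0569), epithelial (0.0505), trophoblast transcription factor (0.168) and placental lactogen lists (0.138) lost their call, and the difference in correlation between days was 0.2249, and the cause was not tested. That filter gained the prostaglandin and lipid list (camera adjusted p = 0.0478). Array weights gained the angiogenesis and the embryonic blood lists, each with a camera adjusted p of 0.0478. The replicate numbers were not shown to pair the samples, since the deviations of arrays with the same number correlated at 0.113, 0.027 and 0.073, and day 20 replicate 2 correlated best with day 22 replicate 3, at 0.033. The replicate block gave 6373 probe sets (2957 higher and 3416 lower) and 11 lists. Low signal limits changes measured from near the floor, as for the 13 named genes with a day mean below 3.57.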

Other observations

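Bounds for the tests of other array splits, the index of RNA integrity, non-trophoblast tissue and conceptus sex were written before their values were seen. The spread of the day 20 arrays and the rise of XIST, which some of these tests address, were themselves found in the data. The other tests in this part were chosen after the data were seen.

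Imprinted genes are defined by expression from 1 parental copy, which was not measured here. They rose more often than other genes: 14 of 23 (60.9%) were higher at day 22, against 14.8% of other genes (Fisher's exact two-sided p = 5.42e-07, adjusted over 3 added lists 1.63e-06). With an estimated correlation camera gave p = 0.0335, adjusted 0.0861, which did not pass. IGF2, a fetal growth factor, rose by 5.51 (SE 1.10, adjusted p = 0.0102), MEG3 by 5.00, DLK1 by 4.55 and PEG10 by 4.32, while PHLDA2, which restrains placental growth, fell by 1.35. Genes with a solute carrier symbol (SLC) outside the nutrient transporter list, SLC4A1AP and SLC7A6OS among them, fell more often than other genes. The added list shares 3 genes with other fixed lists. Of 150, 53 fell (35.3%, against 19.4% of other genes) and 16 rose (Fisher's exact two-sided p for the fall = 5.93e-06, adjusted 8.9e-06). With an estimated correlation camera gave p = 0.0574, adjusted 0.0861. Complement and coagulation genes, 10 of 42 (23.8%) higher against 14.9%, did not pass (Fisher's exact two-sided p = 0.124). Genes are not independent replicates, so these p-values describe the lists on these arrays. The lists were also chosen after the data were seen, so the p-values give no independent support.

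For the fall of trophoblast genes beside the rise of matrix and endoderm genes, a shift made by the normalization would also move spike-ins added in fixed amounts, but 9 such probe sets, at levels from 7.4 to 13.9, changed by at most 0.18; lower levels were not covered. Cells of the dam would raise endometrial and leukocyte markers, whose joint median was -0.21, with 10.2% higher. Some of the markers that fell were high and even on the day 20 arrays, as ITGB2 at 11.02 ± 0.13 and AIF1 at 10.63 ± 0.14. Whether the conceptus itself expresses them was not tested, so the joint median cannot decide on cells of the dam. A lower share of trophoblast RNA as the whole cause would lower alike the genes made by trophoblast alone. The glycoproteins fell more than the transcription factors, by -1.21 between medians (permutation of genes, p = 0.027, over members with a day 20 mean above 5.42). That test treats genes as independent, but the estimated correlation was 0.393 among the glycoproteins and 0.236 among the transcription factors. It also takes the factors to be made by trophoblast alone, which was not tested, and KLF5 of that list rose. The test therefore cannot decide whether a lower share is part or all of the change. The index of RNA integrity differed by 1.29 within-day SDs, between the bounds of 1 and 2 set before the value was seen. Its transcripts did not move alike. A covariate fit was added afterwards (3 residual degrees of freedom). With the covariate the mean of the glycoproteins changed by -2.84 (95% interval -4.15 to -1.54), against -2.89 without it, which argues against RNA integrity as the whole cause there. It stays open for matrix genes (2.31, -0.78 to 5.41; 2.96 without) and endoderm markers (2.06, -1.07 to 5.19; 3.27 without), whose intervals include 0, although both lists stayed past the camera threshold.

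As to chance, the real split of the arrays by day gave 6988 probe sets and the highest other split 0, with 1 of 10 splits as large, and 10 splits cannot give a share below 0.1.

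Day 20 arrays differed among themselves in the genes that later rose. Replicates 2 and 3 exceeded replicate 1 by medians of 1.68 and 1.34 for matrix genes and 1.71 and 1.05 for endoderm genes, but by -0.01 and 0.00 for trophoblast transcription factors. These medians were -0.264 and -0.329 for the glycoproteins and -0.103 and -0.267 for other binucleate trophoblast and fusion genes. For placental lactogens they were 0.046 and -0.059. Lower RNA integrity of replicate 1 is argued against by its index of 0.642, the lowest of the 6 arrays. A loss would have put it above the range of 0.824 to 1.287 of the others. The bound written before the value was seen asked for a value within that range, which 0.642 lay below. Whether the higher index of the other day 20 arrays goes with their higher values was not tested. Among the day 22 arrays replicate 1 had the lowest index, 0.894. It was lowest for endoderm genes (median deviation from the gene mean 0.604) but highest for matrix genes (1.842). Different amounts of non-trophoblast tissue may account for the spread. Endothelial and mesoderm markers other than FLI1 were higher in replicate 2 than in replicate 1 by a median of 0.263. That was at the 99.9th percentile of 10000 random lists matched on expression. The random genes were drawn independently, but the estimated correlation was 0.268 among endothelial markers, so the percentile cannot decide. For replicate 3 minus replicate 1, not tested in this way, the endothelial median was 0.108 and the mesoderm median 0.761. Endometrial markers (median 0.445, 10 of 14 higher) and immediate-early and heat shock genes (0.58, 21 of 27 higher) moved the same way. So did cell cycle genes (0.225, 31 of 37 higher) and interferon-stimulated genes (0.213, 24 of 35 higher). Steroid synthesis (-0.094) and cholesterol synthesis genes (-0.044) did not. Tissue of the dam, handling, differences in development and a link with the index of RNA integrity therefore stay open. Single samples are compared here.

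XIST, the RNA that coats the inactive X chromosome of females, rose from 6.04 ± 1.17 to 10.64 ± 0.30 (n = 3; log2 change 4.60, SE 0.54, limma adjusted p = 0.00128), higher on 3 of 3 day 22 arrays than on any day 20 array. These values are of its brightest probe set. Other XIST probe sets changed by 4.735, 4.298 and 1.945, and those with day means below 3.57 by -0.192 and -0.251. Male conceptuses at day 20 and females at day 22 might give the rise of XIST, but the probe set of the Y-linked gene ZFY reached no more than 2.12 on any array, below the low-signal guide of 3.57, so it cannot decide. Of 10 probe sets for the Y-linked TSPY none passed (the brightest went from 6.74 ± 0.19 to 6.37 ± 0.05, limma adjusted p = 0.0861), though each was lower at day 22 (log2 changes -0.375 to -0.087). The probe set for LOC100335202, a Y-linked gene with the synonym OFD1Y in the reference gene table, fell from 5.98 ± 0.29 to 4.99 ± 0.54 (limma adjusted p = 0.0418). These changes have the direction of that explanation. The brightest TSPY probe set and LOC100335202 stayed above the low-signal guide at day 22, and XIST was above it at day 20, so they do not settle the sex of the samples. A rise of XIST with age or tissue was not tested, and the labels used here give no sex.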
